A study of Mus musculus with 23 samples.

How the data were processed

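The measured material was total RNA of sorted lung cells, prepared with the nCounter mouse miRNA sample preparation kit and read on the mouse miRNA panel, per the labels' protocols. The submitters' processing notes name the genome build mm10 and no tool. The normalization and background treatment are not given in the sources used here. The 1 deposited table holds 626 rows in 23 columns, 602 mature microRNA probes, 14 ERCC control rows, 6 ligation control rows and 4 messenger RNA rows. Columns were assigned to samples by the sample descriptions in the labels, and samples to 12 groups by the cell type and age in the labels.

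The values deposited by the authors are a signal, the nCounter counts of each sample times 1 factor per sample, as the values themselves show. In each column the microRNA, ligation and messenger RNA values are multiples of 1 step, and 99.97% of 13861 values came out whole within a tolerance of 0.1 (4 did not). The step, or factor, ranged from 0.296 to 7.93. In 9 columns values under 1 had been set to 1. The ERCC rows are whole numbers that were not scaled. The geometric mean of the 100 highest microRNAs lay between 537 and 619 in every sample, as a scaling to such a mean would give. A sample with a larger factor has its background counts raised by the same factor, so microRNAs near background appear higher in it. Mean background after scaling ranged from 2.53 to 38.6.

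Of the ERCC rows, 6 form a graded series and 8 are low, and the 8 were taken as negative controls. A microRNA was tested if its recovered count was above the mean plus 2 SD of those 8 rows in at least 2 samples, which 302 were. Precision is set by the counts per sample (26640 to 571715 for microRNAs) and by 1 to 3 samples per group. In AT2 P28 replicate 1 the 6 graded rows summed to 2190 and the 8 low rows were all at 1 count, so its background limit is 1 count. Intervals on shares are 95% Wilson intervals and cover counting error only.

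Because the values are scaled, the main test was limma 3.58.1 (lmFit and eBayes with an intensity trend, R 4.3.3) on log2(value + 1) with 1 mean per group over all 23 samples. Fold changes are on that scale, which understates changes of low microRNAs. Contrasts gave AT2 minus EC averaged over 6 stages, late (P7, P14, P28) minus early (E16.5, E18.5) in each cell type, the difference of these, and each stage minus the one before. Moderated F-tests asked for any difference among the stages. P-values are two-sided and Benjamini-Hochberg adjusted, with 0.05 as the threshold. Groups of 1 sample borrow the spread of the other groups. The labels do not say that samples came from separate animals, so p-values measure the spread between these samples, which may be technical. The limma contrasts and F-tests, the samples in them and the rule for named microRNAs were fixed before the data were examined. The exact tests of the messenger RNA rows, of the MIMAT0000138 share and of the number of microRNAs above background were not part of that plan.

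Messenger RNA rows were named through a RefSeq gene table by accession without version (4 of 4 matched) and tested with exact permutation tests, with differences between cell types taken within the 9 title IDs that both carry, which match the stage. The same table pairs 0 of the 602 microRNA identifiers with a name. The rule for named microRNAs took the highest and lowest changes past the threshold whose higher side was above the background level, and was kept with 2 per direction in place of 8, 5 or 3. MIMAT0003484 was singled out after its values were seen. The 20 microRNA lists fixed in advance, by name, could not be matched, so 0 were tested: endothelial, epithelial (miR-200 family and miR-183 cluster), multiciliated, mesenchymal, leukocyte and erythroid markers, and 13 lists of families, clusters or single microRNAs.

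The limma and edgeR steps were tested on simulated counts for the 302 microRNAs with 200 changed. For AT2 versus EC limma recovered 89% of the 100 changed 2-fold and 100% of the 100 changed 4-fold, and called 5 of 102 unchanged. For AT2 late versus early it recovered 70% and 100%, and called 2 of 102 unchanged. The simulated counts had a minimum of 1 count but no background added. False calls that arise from background multiplied by the sample factors are therefore not covered by these figures. Where a side of a comparison was below background, a bound between geometric means was computed by setting each of its samples below the background limit to that limit. The position of a sample between the cell types used microRNAs differing at least 4-fold in a fit without EC P1 replicate 1, EC P14 replicate 2 and EC P28 replicate 2, leaving out MIMAT0000381 and MIMAT0003168. Alternatives changed the scaling, filter, pseudocount (10), trend, weights, specimen block, title prefix and left-out samples. Those chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood test on the recovered counts), background subtraction, a common floor at the highest scaled background limit (95.1), 3 sets of left-out samples, 2 filters (a mean above the common floor, and above background in all samples), and 3 other scalings of the messenger RNA rows. Background subtraction also used the pseudocount of 10. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.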

Results

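Expression of microRNAs was measured on a NanoString nCounter mouse panel, which counts probe barcodes without amplification, in cells sorted from the lungs of wild-type C57BL6 mice. The 23 samples were, by their labels, endothelial cells (EC, sorted on CD31 by their descriptions) and type II pneumocytes (AT2, sorted on CD326). Type II pneumocytes are the surfactant-producing cells of the alveolus. The labels use this name at every stage, also before birth, and the mix of cells in each sorted sample was not measured here. Cells came from 6 stages, embryonic days 16.5 and 18.5 (E16.5, E18.5) and postnatal days 1, 7, 14 and 28 (P1, P7, P14, P28). AT2 cells had 2 samples at each stage except P28, with 3. EC had 2 samples at each stage except E18.5 and P1, with 1 each. Recovered microRNA counts ranged from 26640 in AT2 P28 replicate 1 and 36373 in EC E18.5 replicate 1 to 571715 in EC P1 replicate 1. Of 602 microRNA probes, 302 passed the background filter and were tested, and 248 were above background in no sample. The files do not pair the probe identifiers with microRNA names, so microRNAs are given by identifier, at most 2 per direction in a comparison. A check of the sorting by named endothelial and epithelial microRNAs was therefore not made.

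The first comparison asks how the microRNAs of the 2 lung cell types differ. MIMAT0000138 took 37.2% ± 6.73 of the microRNA counts in EC (SD, n = 10) and 2.61% ± 2.53 in AT2 cells (SD, n = 13). Over the 9 specimen IDs carried by both cell types, its share was lower in AT2 cells in all 9, by a mean of -33.7 percentage points (exact sign-flip permutation test, two-sided, p = 0.00391, the smallest this design allows, adjusted p = 0.0234 over 12 tests). MIMAT0000138 was chosen from these same samples, where it was the highest microRNA of every EC sample. The p-values of its share do not allow for that choice. On the log2 scale MIMAT0000138 fell by 5.27 ± 0.48 (SE) and MIMAT0000137 fell by 5.04 ± 0.52 from EC to AT2 cells, and each was lower in all 13 AT2 samples than in any of the 10 EC samples (limma, adjusted p = 6.03e-08 and 3.10e-07). In the other direction, MIMAT0001542 was above background in 13 of 13 AT2 samples and 3 of 10 EC samples. It was higher in AT2 cells in all 9 specimen IDs, with a log2 difference of 4.44 ± 0.44 (limma, adjusted p = 2.15e-07), at least 8.63-fold when EC samples below their background limit were set to that limit (this and later bounds are between geometric means).

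**Figure D1:**
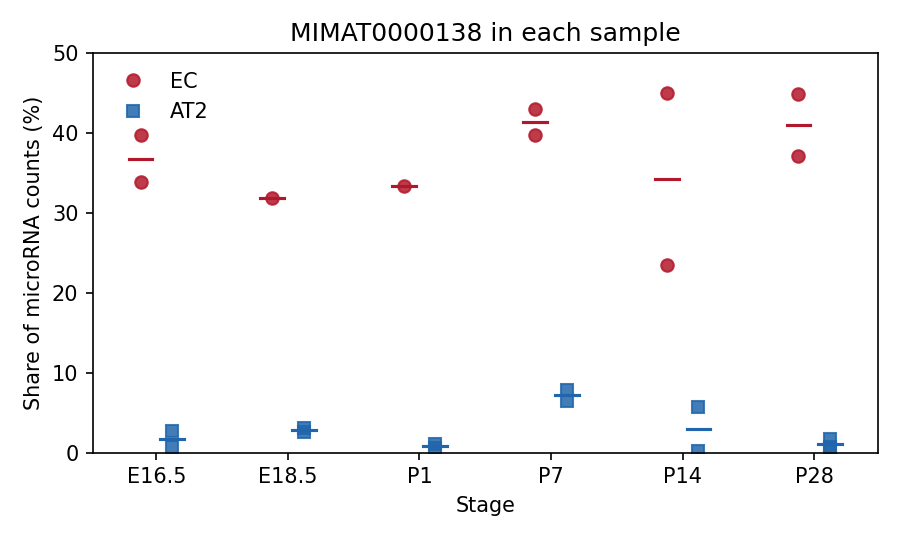
Share of all microRNA counts (%) taken by MIMAT0000138, by stage, in EC (circles) and AT2 cells (squares); each point is a sample and each short line the mean of its group. The EC samples lie between 23.4% and 44.9%, and the AT2 samples between 0.16% and 7.82%.

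More microRNAs were above the background of their sample in AT2 cells than in EC. In AT2 samples 230 ± 28.7 microRNAs were above background, against 176 ± 32.2 in EC (SD, n = 13 and 10), with more in the AT2 sample of all 9 specimen IDs (exact sign-flip test, p = 0.00391, adjusted p = 0.0234). AT2 P28 replicate 1, whose ID is among the 9, stood at 244 with a background limit of only 1 count. The background limit differed between the cell types, with a mean scaled background of 21.0 ± 12.1 in EC and 7.45 ± 6.20 in AT2 cells. At 1 limit for all samples, the highest scaled background limit (95.1), the AT2 samples no longer had more. The mean difference over the 9 IDs was -4.89, and the AT2 sample had more in 3 of them (exact sign-flip test, p = 0.137). MIMAT0000381 had a fitted log2 difference of 4.85 ± 0.72 in favour of AT2 cells (limma, adjusted p = 1.60e-05), which takes EC values below background at face value. It was above background in 8 of 13 AT2 samples and at 2 counts or fewer in all 10 EC samples, so its values were at least 2.44-fold higher in AT2 cells, with EC samples set to their background limits. The bounds given for MIMAT0000381 and MIMAT0003168 hold only if nothing was subtracted from these probes before deposit, which is open. MIMAT0000381 was higher in the AT2 sample of 5 of the 9 specimen IDs. The 8 AT2 samples were all postnatal.

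Across the 302 microRNAs, 203 differed between the cell types, 59 higher in AT2 cells and 144 higher in EC (limma, Benjamini-Hochberg adjusted p under 0.05), and 130 of them differed by 2-fold or more. Of the 203, 154 kept their direction at all 6 stages, 44 of these higher in AT2 cells and 110 higher in EC, and 97 kept it in all 9 specimen IDs. The balance of the 2 directions depended on the scaling. The median log2 difference over all tested microRNAs was -0.43 as deposited. With every sample shifted to the same median, 88 microRNAs were higher in AT2 cells and 102 in EC. Quantile normalization gave 98 and 80, edgeR on the recovered counts 90 and 102, and subtraction of the mean background 92 and 80. With all values below the highest background limit raised to that limit, a common floor, 48 were higher in AT2 cells and 62 in EC, 103 of these 110 were among the 203, and 68 of the 203 were level at the floor. Of the 203, 21 turned direction with quantile normalization and 24 with background subtracted, 2 of these past the threshold.

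**Figure D2:**
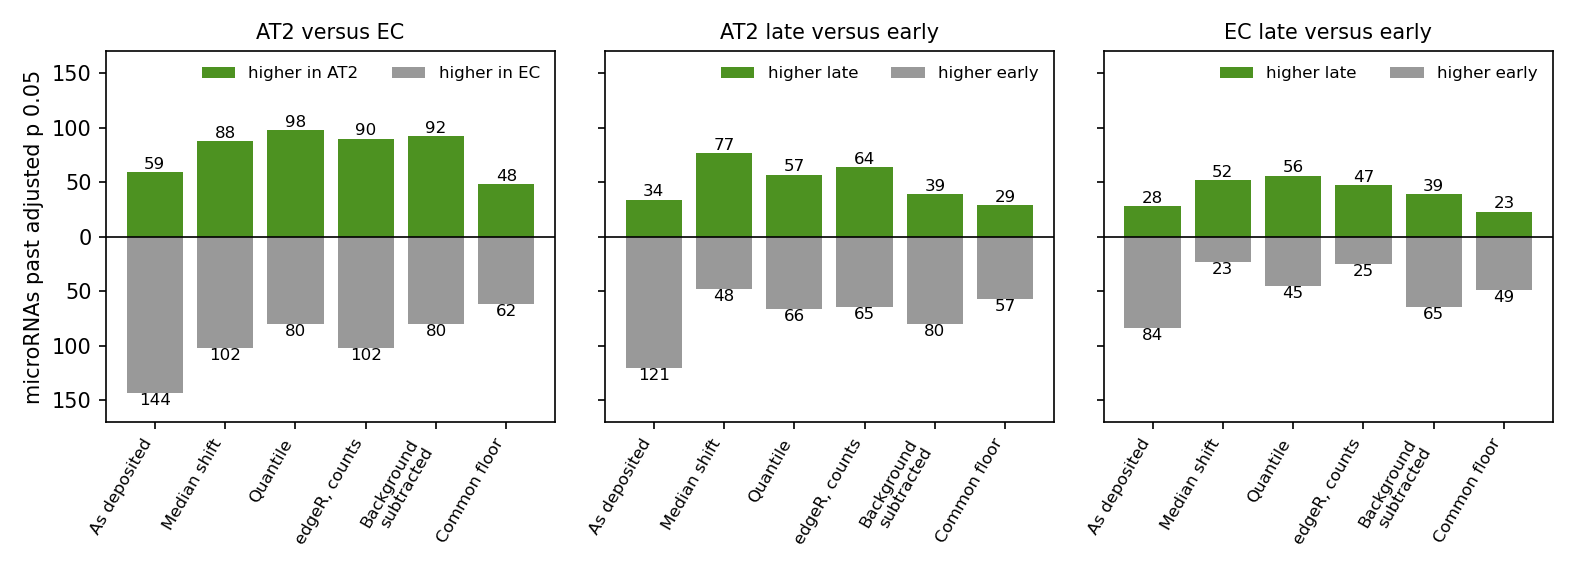
Number of microRNAs past an adjusted p of 0.05 (vertical axis; bars above 0 are higher in the first-named group, bars below 0 lower) for 3 comparisons under the deposited scaling and 5 alternatives. For AT2 versus EC the deposited scaling gives 59 and 144, and background subtraction 92 and 80.

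EC P14 replicate 2 stood apart from the other EC samples. Across the tested microRNAs, 22 of the 23 samples correlated best with a sample of their own cell type, and EC P14 replicate 2 correlated best with AT2 P7 replicate 2 (Pearson r = 0.958, across microRNAs). Of 14 microRNAs at least 4-fold higher in AT2 cells, 13 were above the mean of the EC reference samples there, and their median lay 49.5% of the way from EC to AT2 levels (interquartile range 35.1 to 65.1). The 30 microRNAs at least 4-fold higher in EC stood at a median of 32.5% of their EC mean in that sample, and at 52.8% or more in the other EC samples. The median position of the AT2-high microRNAs was 21.8% in EC P28 replicate 2 and 18.4% in EC P1 replicate 1. Without these 3 samples 213 microRNAs differed between the cell types, 55 higher in AT2 cells and 158 higher in EC, and 194 of the 203 were among them.

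**Figure D3:**
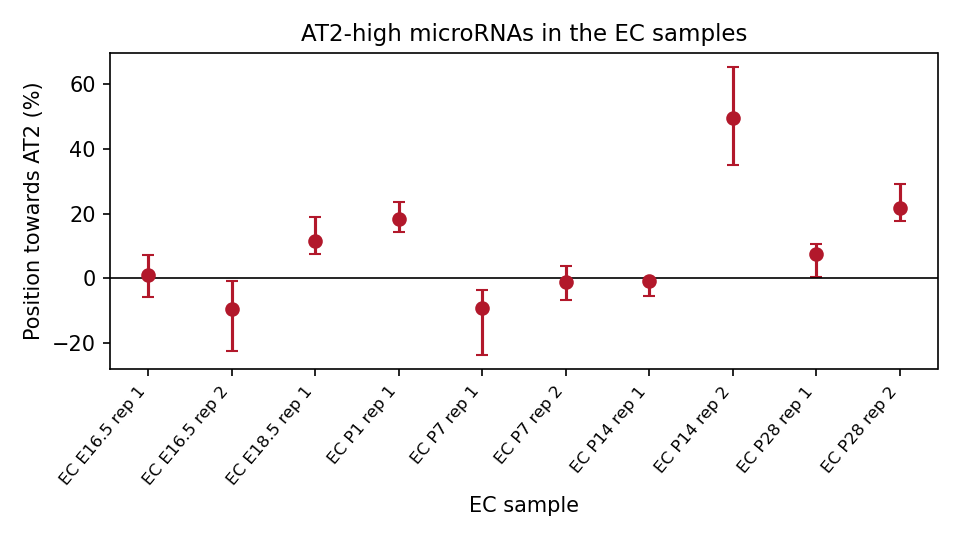
Position of each EC sample (horizontal axis, ordered by stage) between the mean of the EC reference samples (0%) and the AT2 mean of its stage (100%), as the median over 14 AT2-high microRNAs with the interquartile range as bars. EC P14 replicate 2 lies at 49.5%, and the other EC samples between -9.37% and 21.8%.

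The panel also carries probes for 4 messenger RNAs of housekeeping genes. B2m, the light chain of MHC class I, was lower in AT2 cells than in EC in all 9 specimen IDs, by a mean log2 of -3.84 ± 1.47 (SD, n = 9), which is 14.3-fold. Gapdh, a glycolytic enzyme, was also lower in AT2 cells in all 9 (log2 -1.43 ± 0.99), and Actb, cytoplasmic beta-actin, in 8 of 9 (-1.73 ± 1.25). Exact sign-flip tests gave p = 0.00391 for B2m, 0.00391 for Gapdh and 0.00781 for Actb, with adjusted p of 0.0156, 0.0156 and 0.0234 over 12 tests. Rpl19, a protein of the large ribosomal subunit, did not pass (log2 -0.72 ± 1.32, exact p = 0.125, adjusted p = 0.15). In the 18 samples of these IDs all 4 messenger RNAs were above background, though the limit of AT2 P28 replicate 1 was 1 count, where Gapdh held 2 and B2m 12. These values are relative to the microRNA scaling of each sample. Relative to the microRNA total in place of it, B2m (-3.10) and Actb (-0.99) still passed, Gapdh did not (-0.69, exact sign-flip test, adjusted p = 0.0729), and Rpl19 stood at 0.015.

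Gapdh fell from the embryonic stages (E16.5, E18.5) to the later postnatal stages (P7, P14, P28) in both cell types, by 2.39 in AT2 cells and by 2.21 in EC on the log2 scale, and was lower in every later sample than in any embryonic one of its cell type (exact permutation tests, p = 0.00303 and 0.0119, adjusted p = 0.0156 and 0.0238). Rpl19 fell by 1.91 in EC (exact permutation test, p = 0.0119, adjusted p = 0.0238). Both held under 3 other microRNA scalings. All of these relate messenger RNA to microRNA signal. A change of messenger RNA as a whole relative to microRNA therefore cannot be told apart from changes of single genes. Actb fell by 1.36 in AT2 cells (exact permutation test, p = 0.0242, adjusted p = 0.0416), and by the median of the tested microRNAs its change was -0.49 (adjusted p = 0.305 by the exact permutation test). The changes of Actb in EC (-1.71) and of Rpl19 in AT2 cells (-1.33) missed the adjusted threshold (exact permutation tests, adjusted p = 0.0714 and 0.0848). Relative to the microRNA total both passed (-1.75 and -1.56, exact permutation tests, adjusted p = 0.0208 and 0.0273). B2m was at 0.33 in AT2 cells and 0.47 in EC (exact permutation tests, adjusted p = 0.57 for both). By the median of the tested microRNAs its change in AT2 cells was 1.21 (exact permutation test, adjusted p = 0.0468).

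The time course addresses how microRNAs of each cell type change from before birth to 4 weeks of age. In AT2 cells, the values of MIMAT0000381 and MIMAT0000382 rose from the embryonic stages (early, 4 samples) to P7, P14 and P28 (late, 7 samples). MIMAT0000381 was above background in 6 of 7 late and 0 of 4 early samples, a 22.2-fold increase or more against the background limits of the early samples, on the condition above (limma log2 7.81 ± 1.05, adjusted p = 6.48e-06). The late sample that lacked it, AT2 P14 replicate 1, held 1 count. MIMAT0000382 rose by a log2 of 4.04 ± 0.55 (adjusted p = 8.06e-06) and was higher in all 7 late samples than in any early one. MIMAT0003168 fell by 5.59 ± 0.75 and MIMAT0009455 fell by 4.48 ± 0.39 on the log2 scale, and both were lower in all 7 late samples than in any early one (limma, adjusted p = 6.22e-06 and 5.25e-08). Late samples below background set to their limits gave decreases of at least 12.8-fold and at least 15.8-fold. At the common floor the 4 changes were smaller, 3.34, 2.47, -0.89 and -1.54 in the order given, and kept their calls. The floor also removes the spread of values below it, so a kept call there is not separate support. MIMAT0009455 had a smaller change there but a lower adjusted p, 5.76e-09 (limma).

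In total 155 microRNAs changed between the early and late AT2 samples, 34 higher late and 121 higher early (limma). MIMAT0000381 and MIMAT0003168 were at 2 counts or fewer in 15 and 17 of the 23 samples. The median over all tested microRNAs was -0.64, and the balance moved with the scaling, to 77 higher late and 48 higher early with a median shift, 57 and 66 with quantile normalization, 64 and 65 with edgeR on the counts, and 39 and 80 with background subtracted. With the common floor 86 changed, 29 higher late and 57 higher early, 82 of these were among the 155, and 51 of the 155 were level at the floor. With the median shift 15 of the 155 turned direction, and with quantile normalization 9.

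In EC, MIMAT0000535 rose by a log2 of 3.58 ± 0.33 and MIMAT0000128 by 2.50 ± 0.24 from early (3 samples) to late (6 samples), and both were higher in all 6 late samples than in any early one (limma, adjusted p = 7.00e-07 and 1.02e-06). MIMAT0009455, which also fell in AT2 cells, fell by 3.66 ± 0.45 and MIMAT0003456 fell by 2.83 ± 0.40 (limma, adjusted p = 1.60e-05 and 3.40e-05), each lower in all 6 late samples. Late samples below background set to their limits gave decreases of at least 6.38-fold and at least 3.52-fold. At the common floor these 2 changes were -1.42 and -0.50, and kept their calls, again with the spread below the floor removed. The other microRNAs named here also varied with age in AT2 cells. There MIMAT0000535 and MIMAT0000128 had their lowest mean at E16.5 and their highest at P28 (limma F-tests, adjusted p = 3.15e-07 for both). MIMAT0003456 had its highest mean at E18.5 and its lowest at P28 in AT2 cells (limma F-test, adjusted p = 2.37e-05). In EC, 28 microRNAs in total were higher late and 84 higher early (limma), with a median over all tested microRNAs of -0.57. A median shift gave 52 higher late and 23 higher early, quantile normalization 56 and 45, edgeR 47 and 25, and background subtraction 39 and 65. The count fell to 69 without EC E18.5 replicate 1 and to 66 without EC E16.5 replicate 2.

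Many microRNAs changed with age in the same direction in both cell types. The late-minus-early log2 changes of AT2 cells and EC correlated across the 302 microRNAs (Pearson r = 0.67, Spearman rho = 0.70; microRNAs are not independent replicates, so no p is given). Of the tested microRNAs, 18 were higher late in both, against 3.15 for independent lists, and 64 were higher early in both, against 33.7. The values for independent lists leave out the specimen IDs that the cell types share and the scaled background, which was lower late in both: over the 248 microRNAs above background in no sample the median change was -0.68 in AT2 cells and -0.94 in EC. With the common floor, r was 0.66 and rho 0.56, and 14 and 28 microRNAs were shared, against 2.21 and 9.25. Among the late EC samples, EC P14 replicate 2 and EC P28 replicate 2 had raised AT2-high microRNAs (positions 49.5% and 21.8%). The early EC samples lay at 11.4% or less. AT2 RNA in late EC samples could add to the shared direction, and these measures were not computed without them. The change differed between the cell types for 19 microRNAs, 9 more positive and 10 more negative in AT2 cells (limma interaction contrast). MIMAT0003151 moved in opposite directions, rising by 1.39 ± 0.31 in AT2 cells and falling in EC (log2 -2.38 ± 0.36), a difference of 3.77 ± 0.48 (adjusted p = 9.12e-05). For 3 others, MIMAT0000381 (8.97 ± 1.61, adjusted p = 0.00293), MIMAT0003168 (-4.53 ± 1.15, adjusted p = 0.026) and MIMAT0003742 (-2.59 ± 0.66, adjusted p = 0.026), no early or late EC sample was above background. Their differences are therefore fitted values without a bound, and their EC changes of -1.16, -1.06 and -0.98 stand beside the background change of -0.94. With the common floor MIMAT0003151 stood at 3.52 and MIMAT0000381 at 3.34 (adjusted p = 0.0193), MIMAT0003168 at -0.89 without a call (adjusted p = 0.113), and MIMAT0003742 was level (adjusted p = 1). With edgeR MIMAT0000381 (11.73) and MIMAT0003168 (-4.63) did not pass (adjusted p = 0.155 and 0.271). MIMAT0003168 lost its call without single samples at -4.23 to -4.56, and MIMAT0003742 at -2.32 to -2.62. The 19 became 12 with edgeR, 47 with the common floor, 31 without EC P1 replicate 1, EC P14 replicate 2 and EC P28 replicate 2, and 9 without AT2 E16.5 replicate 1.

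Over all 6 stages, 148 microRNAs varied with age in AT2 cells and 82 in EC (limma F-tests), 65 of them in both, against 40.2 for independent lists. The stages of their highest means were unevenly spread. A steady fall or rise has its peak at E16.5 or P28, the ends of the series. In AT2 cells 41 peaked at E16.5, 44 at E18.5 and 41 at P28, and 15 at P1, 5 at P7 and 2 at P14. In EC 30 peaked at E16.5, 23 at E18.5 and 15 at P28, and 10 at P1, 3 at P7 and 1 at P14. With the common floor the F-test called 85 in AT2 cells, 78 of them among the 148, and 59 in EC, 43 of them among the 82. Of the 148, 105 had a stage mean above the floor, with peaks of 29 at E16.5, 23 at E18.5, 13 at P1, 4 at P7, 2 at P14 and 34 at P28. Of the 82 in EC, 63 did, with 24 at E16.5, 10 at E18.5, 10 at P1, 3 at P7, 1 at P14 and 15 at P28. The E18.5 stage of EC is 1 sample, with the highest scaled background limit (95.1). Among the AT2 samples the highest limit was also at E18.5 (57.2, replicate 2). The EC count fell to 51 without EC E16.5 replicate 2.

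**Figure D4:**
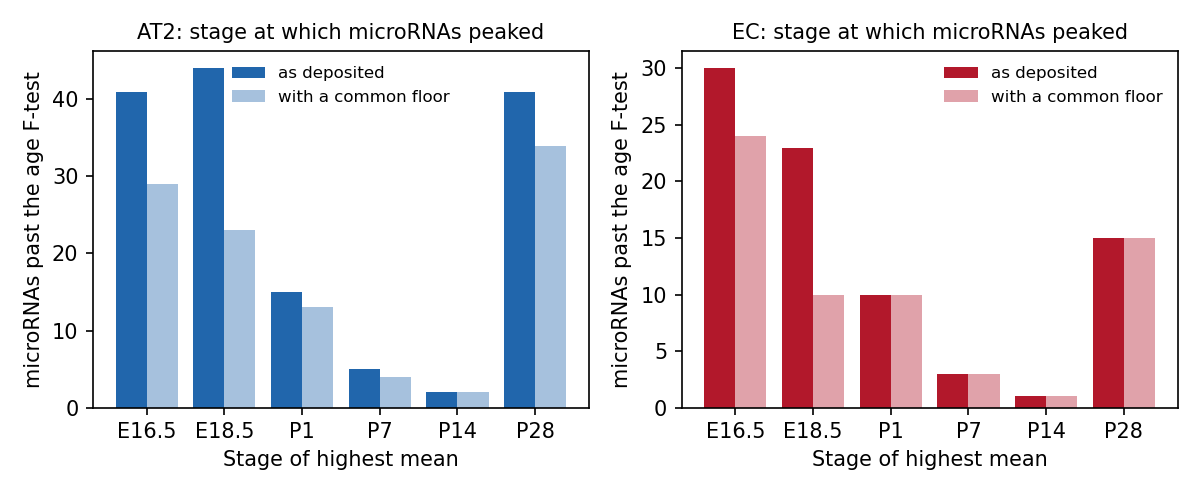
Number of microRNAs past the age F-test (vertical axis) by the stage of their highest mean, in AT2 cells (left) and EC (right), as deposited and with values below the highest background limit raised to it. Few peak at P7 or P14, with 5 and 2 in AT2 cells and 3 and 1 in EC.

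From E18.5 to P1 in AT2 cells 26 microRNAs changed, 8 upward and 18 downward (limma), the most of any step between neighbouring stages as deposited. Another step had more in 6 of 41 alternatives. EC E16.5 to E18.5 had 27 with background subtracted and with quantile normalization, against 17 and 21 for this step, and EC E18.5 to P1 had 191 without a filter, against 142. EC P14 to P28 had 14 with the title prefix as a term, and 8 without AT2 E18.5 replicate 2 or without AT2 P1 replicate 2. MIMAT0000381 and MIMAT0000535 rose by fitted log2 values of 8.45 ± 1.66 and 2.46 ± 0.44 (adjusted p = 0.00809 and 0.00619). The first was below background in both E18.5 samples, so its increase is at least 30.8-fold on the condition above. MIMAT0003168 fell by 4.33 ± 1.18 and MIMAT0000230 fell by 2.67 ± 0.65 (adjusted p = 0.0308 and 0.0196). MIMAT0003168 was below background in 1 of the 2 P1 samples, which on the same condition gives a decrease of at least 9.96-fold between geometric means, or 8.34-fold between arithmetic means, and without AT2 P1 replicate 1 its change was -2.16 (adjusted p = 0.223). It also lost its call with the common floor (-1.03, adjusted p = 0.102), a median shift (-3.69), quantile normalization (-3.43) and edgeR (-2.47). Both E18.5 samples carry title IDs that begin with 15 and both P1 samples IDs that begin with 16. With this prefix as a term limma called 0 microRNAs for this step (37 at an unadjusted p under 0.05), with MIMAT0000381 at 8.66, MIMAT0000535 at 1.90, MIMAT0003168 at -3.52 and MIMAT0000230 at -1.79. Without AT2 E18.5 replicate 2 it also called 0 (45 at an unadjusted p under 0.05), with the 4 changes at 8.80, 2.49, -4.92 and -2.68. Without AT2 P1 replicate 2 it called 4, and edgeR called 29, 19 upward and 10 downward. The other AT2 steps gave 2, 2, 0 and 6 microRNAs in time order. In EC the 5 steps gave 0, 4, 1, 0 and 8, where E18.5 and P1 have 1 sample each. For the steps with 0, AT2 P7 to P14, EC E16.5 to E18.5 and EC P7 to P14, limma gave 22, 44 and 43 at an unadjusted p under 0.05, and edgeR called 0 in each.

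From P14 to P28 in EC, MIMAT0000536 rose by 2.27 ± 0.36 and MIMAT0000127 by 1.80 ± 0.42, while MIMAT0000567 fell by 2.49 ± 0.49 and MIMAT0000747 fell by 2.35 ± 0.48 (limma, adjusted p = 0.00165, 0.0325, 0.0114 and 0.0129). MIMAT0000567 was below background in 1 of the 2 P28 samples and MIMAT0000747 in both, which gives decreases of at least 2.81-fold and at least 3.51-fold. With the common floor their changes were -0.48 and -0.63 (limma, adjusted p = 1 for both). Both of the decreases lost their calls without EC P14 replicate 2 (log2 -1.92 and -1.72), and without the 3 EC samples with raised AT2-high microRNAs (-2.38 and -1.14, adjusted p = 0.0732 and 0.709), while the 8 calls of this step became 4, all upward, without EC P14 replicate 2. MIMAT0000567 also lost its call without EC P28 replicate 1 (-2.04, adjusted p = 0.0811), and MIMAT0000747 without EC P28 replicate 2 (-1.78, adjusted p = 0.215). The call of MIMAT0000127 was lost without EC P14 replicate 1 (log2 1.01), without either P28 sample, with edgeR (log2 1.45), a median shift (1.86, adjusted p = 0.0611) and quantile normalization (1.39, adjusted p = 0.074). With sample weights all 4 lost their calls at unchanged changes (limma, adjusted p = 0.064, 0.132, 0.0818 and 0.114 in the order given).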

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

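All tests of explanations in this part, and the bounds they were read against, were chosen after the values had been seen. Samples far from the others of a set of 4 to 10 samples were sought for 16 measures in 4 sets (all EC, late EC, late AT2, early AT2), and 13 of 64 were found. Chance alone gives about 5 in 100, and the sets span stages. The sets also overlap and several measures are related, so the 13 are not separate findings.

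EC P14 replicate 2 accounted for 5 of the 13. Among the 6 late EC samples its 10 highest microRNAs took 56.7% of counts (others 65.2% to 69.9%) and MIMAT0000138 took 23.4% (95% Wilson interval 23.2 to 23.6; others 37.1% to 44.9%). Its log2 values were 15.56 for MIMAT0000138 (others 16.83 to 17.59) and 10.84 for MIMAT0000137 (others 12.47 to 13.05). Among the 10 EC samples its position towards AT2 levels, 49.5%, was the farthest from the rest (others -9.37% to 21.8%). The EC reference and the microRNAs of this position came from samples without it, left out because its AT2-high microRNAs were raised. Its distance is thus partly built in.

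A swap of EC P14 replicate 2 with an AT2 sample of that stage is argued against, since MIMAT0000138 took at most 5.76% of counts in either AT2 P14 sample. RNA of AT2 cells in this sample is a candidate explanation that cannot be told apart from other causes. The rise of the AT2-high microRNAs is the observation itself, so the EC-high microRNAs were taken as the test. Their median was 32.5% of the EC mean (interquartile range 22.7 to 37.3), lower than in any other EC sample (52.8% or more). Dilution alone would leave 50.5% at a position of 49.5%, if the scaled values of a mixed sample added in proportion. That was not tested, and each sample carries its own scaling factor, so the distance from 50.5% counts neither for nor against AT2 RNA. Named markers could not be matched, and a real difference of this specimen remains open and untested.

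The EC samples had more microRNAs called higher (144) than the AT2 samples (59). Background counts multiplied by larger factors in EC may account for this balance. With each sample's mean background subtracted, 53.5% of the calls were higher in AT2 cells (within 40% to 60%, bounds set after the values were seen). That setting also used a pseudocount of 10, so subtraction was not its only change. Over the 248 microRNAs above background in no sample the median log2 difference was -1.06, AT2 minus EC. A larger set of well-measured microRNAs in EC cannot be told apart from such a background effect: the AT2 samples had more microRNAs above their own background in all 9 IDs, but a mean of -4.89 above the common floor (AT2 minus EC, exact sign-flip test, p = 0.137). Among the calls, 44.7% were higher in AT2 cells in the 127 microRNAs with a mean above the common floor (38 of 85) and 19.2% in the 92 above background in all samples (10 of 52), a filter that favours EC-high microRNAs by its construction. A real excess of EC-high microRNAs also remains open.

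MIMAT0000381 and MIMAT0003168 were at 2 counts or fewer in 15 and 17 of 23 samples and reached 5361 and 341 counts elsewhere. The ordinary background of an undetected microRNA cannot be told apart from other causes by this count, since 7 of the 248 microRNAs never above background were as low in at least 15 samples, against a median of 5 samples. A subtraction applied to single probes before deposit cannot be told apart either: 2.17% of the 46 values lay between 3 counts and the background limit, but 32 of them were at 2 counts or fewer, for which these probes were picked, so at most 30.4% could. In EC P28 replicate 2 MIMAT0000381 was at 1 count, where that sample's position (21.8%) and the AT2 sample of the same ID would put it near 475 in scaled units, if AT2 RNA had carried it in proportion. The size of the rise of MIMAT0000381 in AT2 cells after birth is therefore open, and the bounds given for both probes hold only if no such subtraction was made.

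The late AT2 sample without MIMAT0000381, AT2 P14 replicate 1, was far from the others for it (log2 1.18, others 9.80 to 11.20) and for its position towards EC (-7.81%, others -2.43% to 0.816%). In AT2 P28 replicate 3, MIMAT0003484 took 62.8% of counts (95% Wilson interval 62.6 to 62.9; other late AT2 samples 3.31% to 12.4%) and the 10 highest microRNAs 80.6% (others 43.4% to 52.8%). Among the 4 early AT2 samples, AT2 E18.5 replicate 2 had the highest scaled background (26.6, others 7.29 to 9.52) and a log2 of 1.80 for MIMAT0000381 (others 1.0 to 1.10), below background in all 4. AT2 E16.5 replicate 1 had a MIMAT0000138 log2 of 10.23 (others 12.03 to 12.19), and AT2 E16.5 replicate 2 a MIMAT0003456 log2 of 8.26 (others 8.72 to 8.73).

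The change with age differed between the cell types by the interaction contrast for 19 microRNAs, among them MIMAT0000381 (8.97), MIMAT0003151 (3.77), MIMAT0003168 (-4.53) and MIMAT0003742 (-2.59), all log2 differences of AT2 minus EC. The age change that both cell types share was taken out, and late and early were then redrawn within each cell type. Of 100 such splits 1, the real one, gave as many calls as the 9 of a model with 2 ages (highest other 2), and the 19 of the model with 6 stages were not tested in this way. For AT2 versus EC 1 of 100 splits, the real one, gave as many (204, highest other 27). For AT2 late versus early it was 1 of 100 (126, highest other 5), and for EC late versus early 1 of all 84 (49, highest other 25). A chance split is thus an unlikely source of these 4 counts (9, 204, 126 and 49), within the resolution of 1 in 100 or 1 in 84. The redrawing moved single samples across stages and ignored shared specimen IDs, so effects of specimen or title prefix were not tested by it.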

How the results depend on the processing

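Settings with edgeR, background subtraction, a common floor, a filter on the mean or on background in all samples, sets of left-out samples, or other messenger RNA scalings were chosen after seeing the data. No named microRNA turned its direction: of 996 values under alternatives, 947 kept direction and call and 49 lost the call, among them MIMAT0003742, level at the common floor. Rpl19, not past the threshold, turned from -0.72 to 0.015 (AT2 minus EC) relative to the microRNA total. The 12 named changes of AT2 versus EC and of late versus early kept their calls in every setting that tested them. Counts moved with the number of microRNAs tested: without a filter AT2 versus EC gave 467, EC late versus early 192, the EC F-test 189 and the neighbouring stages together 346 (49 as reported), while a filter at 100 gave 122 for AT2 versus EC. A filter on the mean gave 85 for AT2 versus EC, 76 and 63 for AT2 and EC late versus early, 77 and 53 for their F-tests, and 11 for the difference by cell type. A filter on background in all samples, which favours EC-high microRNAs, gave 52 for AT2 versus EC, 44 and 37 for AT2 and EC late versus early, 44 and 29 for their F-tests, 5 for the difference by cell type and 19 for neighbouring stages. The common floor removes differences below the highest background limit of any sample, including some that are above background in samples with lower limits. The floor also removes the spread of values below that limit, which can keep or add calls. It gave 110 for AT2 versus EC, 86 and 72 for AT2 and EC late versus early, 85 for the AT2 F-test, 47 for the difference by cell type and 99 for neighbouring stages. For the following the cause was not tested. With edgeR EC late versus early gave 72, the difference by cell type 12 and neighbouring stages 83. Neighbouring stages gave 96 with quantile normalization, 77 with pseudocount 10, 153 with sample weights, 26 with the title prefix as a term, and 86 with background subtracted. EC late versus early gave 69 with E16.5 alone as early and 73 without the 2 shallowest samples. Without the 3 EC samples with raised AT2-high microRNAs the difference by cell type gave 31 and neighbouring stages 103.

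Leaving out each sample in turn gave 185 to 212 for AT2 versus EC, 116 to 164 and 51 to 105 for the AT2 and EC F-tests, 115 to 167 and 66 to 123 for AT2 and EC late versus early, 9 to 25 for the difference by cell type and 22 to 129 for neighbouring stages. The samples that moved a count over 1.5 times were EC E16.5 replicate 2 (EC F-test 51, EC late versus early 66), EC E18.5 replicate 1 (EC late versus early 69), AT2 E16.5 replicates 1 and 2 (difference by cell type 9 and 11), AT2 E18.5 replicates 1 and 2 (12 each, and neighbouring stages 22 for the latter), AT2 P7 replicate 1 (10), EC E16.5 replicate 1 (11), AT2 P1 replicate 2 (neighbouring stages 29), AT2 P14 replicate 2 (85) and EC P14 replicates 1 and 2 (129 and 98). Deviations from group means of the EC and AT2 samples with the same ID correlated at -0.02 to 0.31 over 7 IDs, and 5 of 7 AT2 samples correlated best with the EC sample of their own ID, and the 2 IDs of P7 and of E16.5 share a value by construction. The main model had no block, as set before the data were examined, and the labels do not say what an ID is. The correlation was under 0.1 for 1 ID and above 0.2 for the others, so samples of an ID may share part of their variation. The specimen as a random replicate block gave 213 for AT2 versus EC, and as a fixed block over the 9 shared IDs 187. Tests of the microRNA lists and their settings were not run, as the identifiers have no names here, nor was DESeq2, on scaled values. No difference could be measured below background, where 248 of 602 microRNAs lay in every sample; low depth and absence were not separated.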

Other observations

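MIMAT0003484 was singled out after its values were seen. AT2 cells at P1 and P28 included samples in which 1 microRNA, MIMAT0003484, took much of the signal, 34.1% of counts in AT2 P1 replicate 2 and 62.8% in AT2 P28 replicate 3, while it took 3.11% ± 1.16 in EC (SD, n = 10). The other AT2 samples of these stages held 7.85% at P1, and 5.39% and 7.76% at P28.

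B2m spanned 99.3 to 5368 in the EC samples and 5.96 to 210 in the AT2 samples in scaled units, and Gapdh 27.2 to 578.7 and 6.36 to 316.8. The ligation control rows took from 6.3% to 48.3% of the counts of a sample.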
